A study of Homo sapiens with 12 samples.

How the data were processed

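Accessible chromatin was profiled by Omni-ATAC, a transposase-based sequencing assay, in H1 human embryonic stem cells, an established line. The cells carried a lentiviral control shRNA or an shRNA against OTUD5, a deubiquitinase. They were collected as stem cells (hESC) or after 3 days of neural induction (NC3), which gave 4 groups of 3 libraries. Stage, shRNA and replicate of all 12 libraries were taken from the sample labels. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

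Each library had its own deposited peak list, with 4 columns and no header. Whether any step in making a list used data of other libraries is not stated. Coordinates are on hg38, per the submitters' processing notes. The aligner, the peak caller and their settings are not given in the sources used here. The names of the deposited lists carry an IDR of 0.05, read here as a cut on the reproducibility of peaks. How that cut was made, and between which data, is not given. A peak may thus be absent from a list because it failed the cut. The authors' value in column 4 was read as −log10 of a p-value or q-value, because its most frequent values step as −log10 Poisson tail probabilities do. Whether it is a p or a q is not stated in the deposited lists. Such a value is relative to the caller's background for its own list. The column was therefore used here only to rank or filter peaks within a list and was never compared between libraries. The lists hold no reads, so the depth of each library is unknown and no counting interval or lower limit of detection is given. The length of a list, from 39926 to 55701 peaks, is the only measure of how much was called. A region not called in a library is not shown to be closed there.

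Peaks of the 12 lists on chromosomes 1 to 22, X and Y were merged where they overlapped by at least 1 bp. A region counted as called in a library where a peak of its list overlapped it by at least 1 bp. Merging was done in NumPy. Printed coordinates are counted from 1. The annotation at hand was a RefSeq table of gene starts and ends for GRCh38.p14, without strands or transcripts, and no genome sequence. Each region was therefore assigned to the nearest protein-coding gene interval within 100 kb of its midpoint, with distance 0 inside a gene and ties going to the nearer gene end. The plan had named the nearest transcription start site instead. In place of a promoter share, the share of called regions within 1 kb of either end of a protein-coding gene was computed. The planned shares of 18 sequence motifs were not run, since they need a genome and peak summits. Of 284 entries in the gene lists, 284 matched the annotation, 1 of them by an older symbol.

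Stage was compared by Fisher's exact test per region, 6 libraries against 6, two-sided, over the regions whose number of calls could give a p below 0.05. Benjamini-Hochberg adjustment was used throughout, with calls at an adjusted p below 0.05. The shRNAs were compared per region by an exact two-sided permutation test within stage, over 400 labellings with a smallest p of 0.005. Within 1 stage, 3 libraries against 3 cannot give a p below 0.1. There, regions called in 3 of 3 libraries with 1 shRNA and 0 of 3 with the other, named separated regions, were counted and set against the other 9 splits of the 6 libraries. Values per library were compared by exact two-sided permutation of stage (smallest p 0.00216), of the shRNA within stage, and of the shRNA effect between stages. Similarity was the Jaccard index of called regions for each pair of libraries, and its test was an exact one-sided permutation.

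The 12 gene lists were pluripotency, neuroectoderm, neural crest, neuronal differentiation, mesendoderm, surface ectoderm and trophoblast, HOX, targets of TGF-beta, BMP and WNT, targets of YAP, TEAD and AP-1, stromal and mesenchymal cells, chromatin remodellers, and housekeeping genes. For each library, the regions assigned to a list's members were counted per 10000 called regions, with adjustment over the 12 lists. A region counts once for its gene, so these values measure the number of called regions and not the signal within them. Genes were tested by the same permutations where their mean was at least 1 region per library, which left 12478 of 16830 genes with a region. NC3 lists were longer, so scaling to 10000 regions moved genes by −0.164 on the log2 scale at NC3, and the median gene's scaled difference was −0.161. A gene was therefore called only where its adjusted p passed both per 10000 regions and as a plain number of regions, in the same direction. This rule was adopted after the scaled test had given 1222 genes higher and 1570 lower at NC3, against 780 and 315 on plain numbers.

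The named genes follow a fixed rule. For stage, and for the shRNA at each stage, they are the 10 genes per direction with the most called or separated regions net of the opposite direction. Ties went to the higher mean within-list percentile of the column 4 value, then to the symbol. This rule favours long genes. To these were added up to 4 members per list with the largest difference, and OTUD5. The gene lists, the naming rule, the tests per region and per library and most alternatives were chosen before the data were examined. The test per gene and its rule of passing on both scales, the assignment by gene interval, the calls at the other stage, the share of regions also called at the other stage and its test, the comparison of the control and shOTUD5 arms, the enrichment of lists among separated regions and the within-list percentiles were chosen after the data had been explored. List members outside the rule that passed the test per gene were named after their values were seen. A few genes that the rule names were left out of the text because they are withheld for evaluation.

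Alternatives were lists shortened to the 39926 highest-ranked peaks, a minimum column 4 value of 5, at least 50% of a region covered, fixed windows at peak midpoints, regions called in at least 2 libraries, genes within 20 kb, any region within 50 kb of a member, gene ends within 2 kb, plain numbers of regions, the nearest gene end, autosomes alone, adjustment over every region, a stage test stratified by shRNA, shares divided by the share of other regions, the replicate number as a block, and leaving out each library in turn. The tests were run on simulated call tables. Changed regions were drawn from those with intermediate numbers of calls. They were given a near-complete switch, with calls likely in almost every library of a group and in almost none of its counterpart. Recovery of partial changes was not simulated for regions. With 10000 stage-dependent regions among 102500, 88.1% were recovered and 164 others were called, but with 200 such regions none was recovered (0%). For the shRNA over both stages, 53.4% of 1000 changed regions were recovered with 2 others called, and 0% of 200. For separated regions, 1000 changed regions gave 1477 in the labelled split and at most 702 in another for hESC, and 1501 and 800 for NC3. For the test per gene, 99.4% of 1000 genes changed by up to 4-fold were recovered with 4 others called, but 0% of 200. The changed genes were drawn from the 1608 with a mean of at least 5 regions, so recovery among genes with fewer regions was not simulated. A first simulation of the test per gene, with smaller changes in 200 genes, had also recovered none and was replaced by this one. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.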

Results

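Chromatin accessibility was compared between H1 human embryonic stem cells (hESC) and the same line after 3 days of neural induction (NC3), with a control shRNA or an shRNA against OTUD5. Per the series design, the question was how depletion of OTUD5 acts on accessible chromatin in stem cells and during early neural differentiation. Each of the 4 groups held 3 libraries. The lists held 43066 ± 4704 peaks (SD, n = 3) in hESC control, 44514 ± 3717 in hESC shOTUD5, 50169 ± 5482 in NC3 control and 47318 ± 5010 in NC3 shOTUD5. Read depth is unknown. Peak numbers differed by 4953 between stages (exact two-sided permutation p = 0.0823) and by −702 between shRNAs (p = 0.805). Leaving out NC3 shOTUD5 replicate 2, which had the shortest NC3 list, gave a stage difference of 6312 (exact permutation p = 0.0325). Covered sequence rose from 16.3 ± 1.89 Mb in hESC to 20.7 ± 2.55 Mb at NC3 (SD, n = 6, exact p = 0.013). Merging gave 102500 regions with a median width of 433 bp, of which 12965 (12.6%) were called in all 12 libraries and 22262 (21.7%) in 1 library. Of all regions, 48.9% lay inside a protein-coding gene and 83.2% within 100 kb of one.

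The targeted gene, OTUD5 (gene 55593, chromosome X, 48922024 to 48958381), had 3.33 ± 1.53 called regions in hESC control and 3.67 ± 0.577 in hESC shOTUD5 libraries. At NC3 it had 1.67 ± 1.15 and 2 ± 1 (SD, n = 3 each). The exact permutation test of the shRNAs within stage gave p = 0.445. An shRNA acts on the mRNA, so accessibility at the gene does not check the knockdown.

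**Figure D1:**
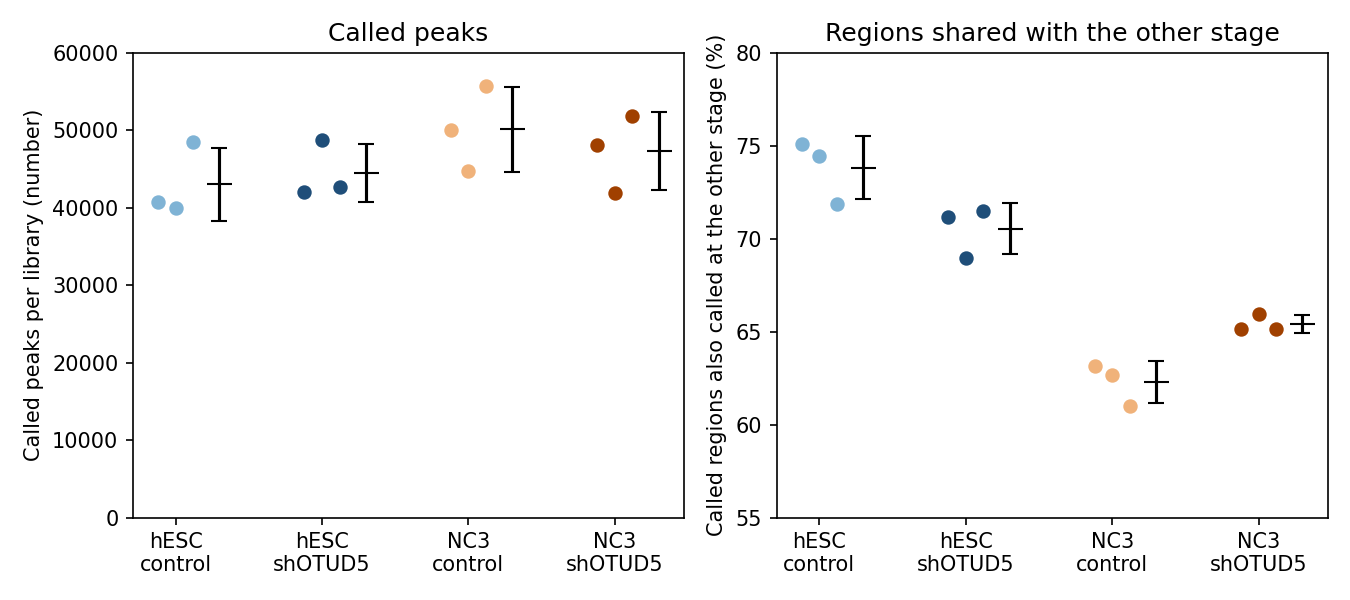
Called peaks per library (left, number) and share of a library's called regions that were also called in at least 1 library of the other stage (right, percent, axis from 55). Each point is 1 library and the bars give the mean and SD of 3; the shares averaged 73.8% and 70.5% in hESC and 62.3% and 65.4% at NC3, control before shOTUD5.

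The first comparison asked what neural induction changed. RBFOX1, a neuronal splicing regulator, had 22.5 ± 5.72 called regions in hESC and 36.8 ± 3.71 at NC3 (SD, n = 6). AUTS2, a gene of neurodevelopmental disorders, rose from 14.7 ± 3.01 to 35.2 ± 3.43, the axon guidance receptor gene ROBO1 from 6.17 ± 2.04 to 18 ± 2.1, and PAX3, a transcription factor gene of neural crest and dorsal neural tube, from 2.67 ± 0.816 to 8.33 ± 2.34. In the other direction, NANOG, a core pluripotency factor gene, fell from 2.5 ± 0.548 regions to 0.5 ± 0.548, and CDH1, which encodes E-cadherin, from 4.83 ± 1.6 to 1.83 ± 0.983, while CDH2, which encodes N-cadherin, rose from 2 ± 0.894 to 6.83 ± 1.72. All of these passed the exact permutation test per gene on both scales.

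Of 24239 regions that could be tested, 17061 differed between stages by Fisher's exact test, 10918 of them called more often at NC3 and 6143 more often in hESC. Their largest adjusted p was 0.0215. Of these, 6840 were called in 6 of 6 NC3 and 0 of 6 hESC libraries, and 3220 the other way round. Lists of equal length gave 8878 NC3-higher and 6676 hESC-higher regions, so the excess at NC3 was smaller there. Stage regions lay away from gene ends: 4.02% of NC3-higher and 5.03% of hESC-higher regions were within 1 kb of a gene end, against 39.1% of the regions called in all 12 libraries. Regions called in 3 of 6 libraries of a stage lay between, at 15% for hESC and 12.9% for NC3. In the control arm alone, 11877 regions were called in 3 of 3 NC3 and 0 of 3 hESC libraries, and 5697 in the reverse. In the shOTUD5 arm the numbers were 10511 and 6434. These differences between arms, −1366 and 737, were within what other labellings gave (exact two-sided permutation p = 0.48 and 0.55).

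Among genes, 767 had more called regions at NC3 and 315 had fewer, out of 12478 tested. Besides RBFOX1 (chromosome 16, 5239721 to 7713340; 17 NC3-higher and 4 hESC-higher regions) and AUTS2 (chromosome 7, 69598475 to 70793506; 16 and 3), the genes with the most NC3-higher regions were MACROD2, RAD51B, CTNNA2, MSI2, CNTNAP2, SOX5, ROBO1 and DPYD. MSI2, an RNA-binding protein gene, rose from 10.3 ± 2.42 to 22.5 ± 1.87 regions, SOX5 from 11 ± 2.45 to 20.3 ± 3.14 and DPYD, of pyrimidine breakdown, from 4.33 ± 1.21 to 16.5 ± 2.35. MACROD2 rose from 18.3 ± 1.51 to 30 ± 4.15, RAD51B from 17.5 ± 2.43 to 29.7 ± 3.14 and CTNNA2 from 15.7 ± 2.58 to 24.5 ± 2.43. CNTNAP2 had 29 ± 3.41 and 34.5 ± 2.17 and did not pass (exact permutation, adjusted p = 0.353 scaled and 0.0876 unscaled). Adjusted p was 0.0274 or lower per 10000 regions and 0.0493 or lower on plain numbers for the others.

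Among the genes with the most hESC-higher regions were FOXN3, KLF12, MKLN1, ABHD2, MDN1, PREX2, PDE10A, HS3ST5 and GORAB. FOXN3, a forkhead transcription factor gene, fell from 16.2 ± 1.72 to 12.2 ± 1.17 regions, MKLN1 from 9.17 ± 0.753 to 3.83 ± 1.6 and ABHD2 from 10.8 ± 2.14 to 4.67 ± 1.51 (SD, n = 6). MDN1, of ribosome assembly, fell from 7.67 ± 0.816 to 1.67 ± 0.516. PREX2 fell from 9.5 ± 1.38 to 4.67 ± 1.97, PDE10A from 11.5 ± 1.38 to 6 ± 2.1 and GORAB from 6.17 ± 0.753 to 2.83 ± 0.753. KLF12, with 17.2 ± 1.94 and 12.7 ± 3.83, did not pass on either scale, and HS3ST5, with 8.67 ± 1.51 and 6.5 ± 0.837, did not pass on plain numbers (exact permutation, adjusted p = 0.156).

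Among the gene lists, regions at pluripotency genes fell from 17.8 ± 1.32 to 11.1 ± 1.08 per 10000 called regions (SD, n = 6), and 0 of its 21 tested members rose, 4 fell and 17 did not pass. The 4 were NANOG, CDH1, LEFTY1, a NODAL inhibitor gene with 2 regions in hESC and 0.667 ± 0.516 at NC3, and TERF1, with 2.17 ± 0.408 and 1. Adjusted over the list alone, 1 rose and 6 fell. Neuroectoderm regions rose from 21.9 ± 1.84 to 27.8 ± 1.33, with 3 members up, 0 down and 25 not passing (7 up and 1 down adjusted over the list alone). These were CDH2, GLI3, the hedgehog pathway factor gene, which rose from 12 ± 2 to 20.7 ± 2.8, and SFRP1, a WNT inhibitor gene, which rose from 4.33 ± 0.816 to 8.5 ± 1.52. MEIS1 had 6 ± 1.41 and 11.2 ± 2.32, and OTX2 7.17 ± 1.17 and 4 ± 1.1, without passing on plain numbers (exact permutation, adjusted p = 0.0615 each). These list shifts had an exact permutation adjusted p of 0.00325, and in each all 6 NC3 libraries lay on the same side of all 6 hESC libraries.

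Neural crest regions rose from 18 ± 0.95 to 25.8 ± 1.18 per 10000 called regions (SD, n = 6, exact permutation adjusted p = 0.00325), with 8 members up, 0 down and 10 not passing (8 and 0 adjusted over the list alone). TFAP2B rose from 1.67 ± 0.816 to 6.33 ± 0.516 regions and the endothelin receptor gene EDNRB from 1.67 ± 0.516 to 6.17 ± 0.983, and PAX3, PAX7, SOX5, SOX9, MSX1 and MSX2 also rose. Targets of TGF-beta, BMP and WNT rose from 14.9 ± 1.04 to 19.8 ± 0.753 (adjusted p = 0.00325 by exact permutation), with 8 members up, 0 down and 12 not passing (10 and 0 adjusted over the list alone). The WNT feedback gene AXIN2 rose from 3.67 ± 1.21 to 9.67 ± 1.21, NKD1 from 2.67 ± 1.03 to 7.33 ± 2.16 and the BMP-responsive MSX1 from 0.5 ± 0.837 to 4.17 ± 0.753. MSX1 and MSX2 belong to both lists. Mesendoderm regions rose from 10.4 ± 0.712 to 13.5 ± 1.09 (adjusted p = 0.00325 by exact permutation), with 1 member up, 0 down and 17 not passing (1 and 0 adjusted over the list alone). That member was GATA6, an endoderm factor gene, with 0.167 ± 0.408 and 2.5 ± 0.837 regions.

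HOX, chromatin remodeller and housekeeping lists passed per 10000 called regions but not on plain numbers of regions, where the differences were −3, −4.5 and −5 regions per library. HOX went from 2.08 ± 0.503 to 1.22 ± 0.141 (SD, n = 6, exact permutation adjusted p = 0.00325 and, on plain numbers, 0.0631), with 0 of 2 tested members passing and, adjusted over the list alone, 1 up and 0 down. Chromatin remodellers went from 16.7 ± 0.616 to 14 ± 0.505 (adjusted p = 0.00325 and 0.394 by exact permutation). Of their members, ARID2 (2.5 ± 0.837 to 6.5 ± 1.05) and CREBBP (0 to 2 ± 0.632) rose, 2 fell, among them SMARCA2 (10.7 ± 1.75 to 6.5 ± 1.05), and 15 did not pass, with 2 and 2 adjusted over the list alone. Housekeeping genes went from 9.05 ± 0.414 to 6.98 ± 0.531 (adjusted p = 0.00325 and 0.13 by exact permutation), with TFRC down from 5.5 ± 0.548 to 3 ± 0.894, 0 up and 16 not passing (0 and 1 adjusted over the list alone).

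Neuronal differentiation regions were at 11.7 ± 0.909 and 13.4 ± 1.42 per 10000 called regions (SD, n = 6), which missed the threshold (exact permutation adjusted p = 0.0548). Without NC3 shOTUD5 replicate 2 the difference was 2.23 with an exact adjusted p of 0.00325. Leaving out any other library did not pass, with exact permutation adjusted p from 0.0519 to 0.107. Of its members, 2 rose, among them the neuronal factor gene ISL1 (0.5 ± 0.548 to 4.5 ± 0.837), 1 fell, ONECUT1 (5.17 ± 1.17 to 1.83 ± 0.753), and 13 did not pass (2 and 1 adjusted over the list alone). The 3 remaining lists did not pass. Surface ectoderm and trophoblast genes were at 8.85 ± 0.836 and 8.77 ± 0.783, with 0 of 15 members passing, also when adjusted over the list alone. Stromal and mesenchymal genes were at 10.6 ± 0.969 and 10.4 ± 1.25, with 0 of 14 passing, also when adjusted over the list alone. Targets of YAP, TEAD and AP-1 were at 14.7 ± 0.949 and 14.8 ± 1.29, with ATF3, a stress-response factor gene, up from 1.33 ± 0.516 to 6.5 ± 1.38, 0 down and 15 not passing (1 and 0 adjusted over the list alone). For these 3 lists the exact permutation adjusted p was 0.903. Counting any region within 50 kb of a member gave 1.45 for surface ectoderm and trophoblast (exact adjusted p = 0.0462), and genes within 20 kb gave −1.53 for targets of YAP, TEAD and AP-1 (exact adjusted p = 0.0195). The share of called regions near gene ends was 21.6 ± 0.449% in hESC and 20.2 ± 0.514% at NC3 (difference −1.39, exact permutation p = 0.00216), but with lists of equal length the difference was −0.453 (p = 0.387).

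**Figure D2:**
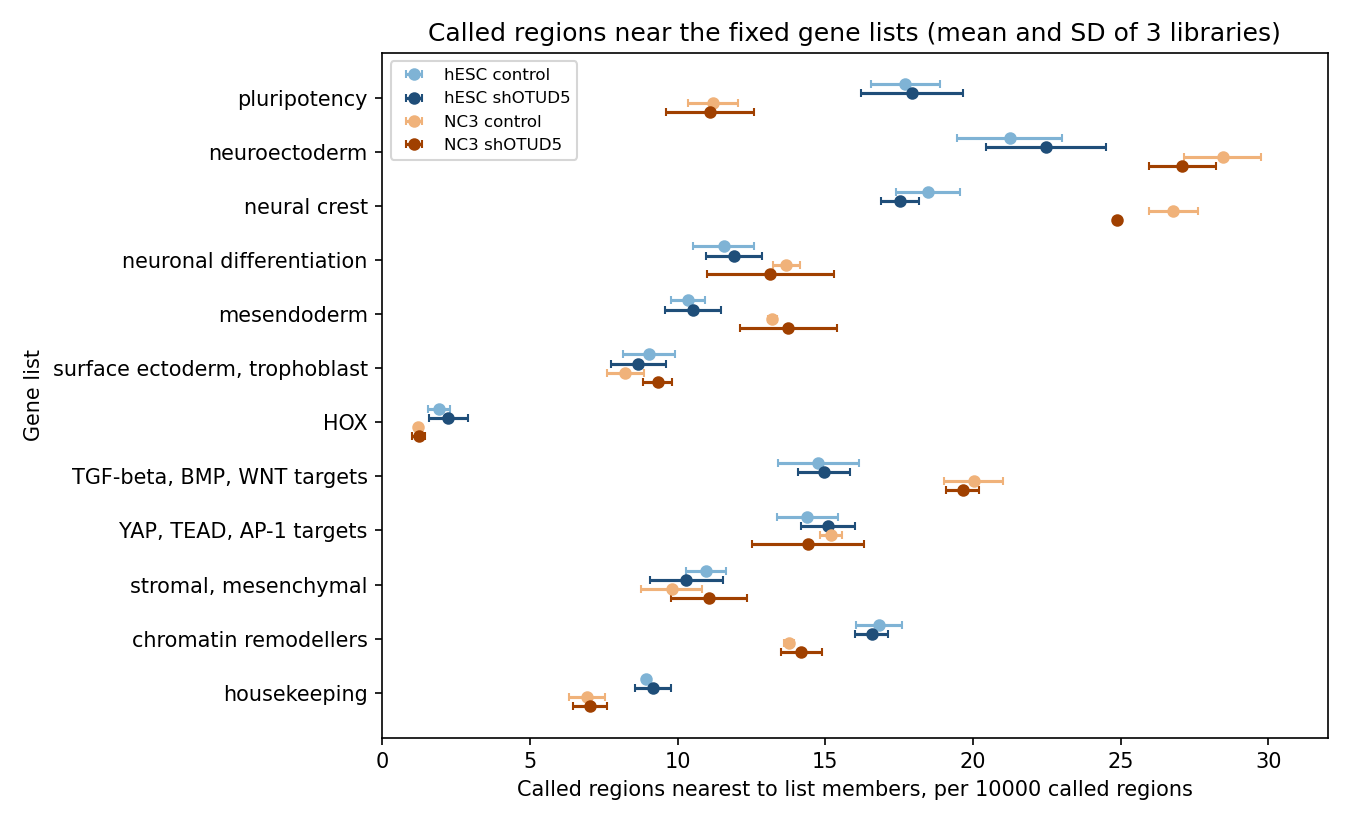
Called regions assigned to each of the 12 gene lists, per 10000 called regions, as the mean and SD of the 3 libraries of each group. Pluripotency regions were fewer and neural crest and neuroectoderm regions more numerous at NC3 than in hESC. HOX, chromatin remodeller and housekeeping lists, lower at NC3, did not pass on plain numbers of regions. No list passed between the shRNAs, where a list that differs alone could not pass.

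The second comparison asked where shOTUD5 and control cells differed at NC3. There, 1531 regions were called in 3 of 3 control and 0 of 3 shOTUD5 libraries, and 748 the other way round. Regions called only with the control shRNA were most numerous at ADGRL3, an adhesion receptor gene of neurons (4 and 0 in reverse), PTPRD, a receptor phosphatase gene of synapses (4 and 1), and SLIT3, an axon guidance ligand gene (4 and 1). ST8SIA2, which encodes a polysialyltransferase acting on NCAM, AUTS2, FRYL, ERC1, STARD13, LRMDA and MAML3 had 3 each and 0 in reverse. Regions called only with shOTUD5 were most numerous at LRP1B (4), KLF12 (3) and SSBP3 (3), followed by TCERG1L, RERE, CCDC71L, CDK14, BICC1, GPHN and RGS3 with 2 each. For AUTS2 the control-only regions lay at 70040535 to 70040918, 70239997 to 70240331 and 70267333 to 70267742 on chromosome 7, none of them called in any hESC library. At KLF12, the region at 74036394 to 74036847 on chromosome 13 was called in all 6 hESC libraries, and the other 2 shOTUD5-only regions, at 73730068 to 73730463 and 74287898 to 74288066, in none. The total number of called regions per gene was 38 ± 1 and 32.3 ± 2.08 at AUTS2, 37.3 ± 3.51 and 30.3 ± 1.15 at PTPRD, 9.33 ± 0.577 and 16 ± 1.73 at KLF12 and 14.3 ± 3.06 and 20.7 ± 1.53 at LRP1B, control before shOTUD5 at NC3 (SD, n = 3). At other named genes the totals were closer, such as 17.7 ± 0.577 and 16.7 ± 2.52 at LRMDA, 22.3 ± 3.51 and 21 ± 1.73 at CDK14, and 5.33 ± 1.53 and 5.67 ± 1.53 at BICC1. These totals include the separated regions by which the genes were picked, so they are no separate evidence of a difference.

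Together, 2279 regions separated the shRNAs at NC3, or 28.6% of the 7981 regions with calls in 3 of 6 libraries, where chance gives 10%. The other 9 splits of these libraries gave at most 1025. With lists of equal length the directions were closer, at 1200 control-only and 935 shOTUD5-only, 2135 in all against at most 583 in another split. Separated regions ranked low within their lists, with a median percentile of 30.8 for control-only and 27.7 for shOTUD5-only regions, against 75.8 for regions called in all 12 libraries. A single region cannot pass a test of 3 libraries against 3, whose smallest exact permutation p is 0.1.

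**Figure D3:**
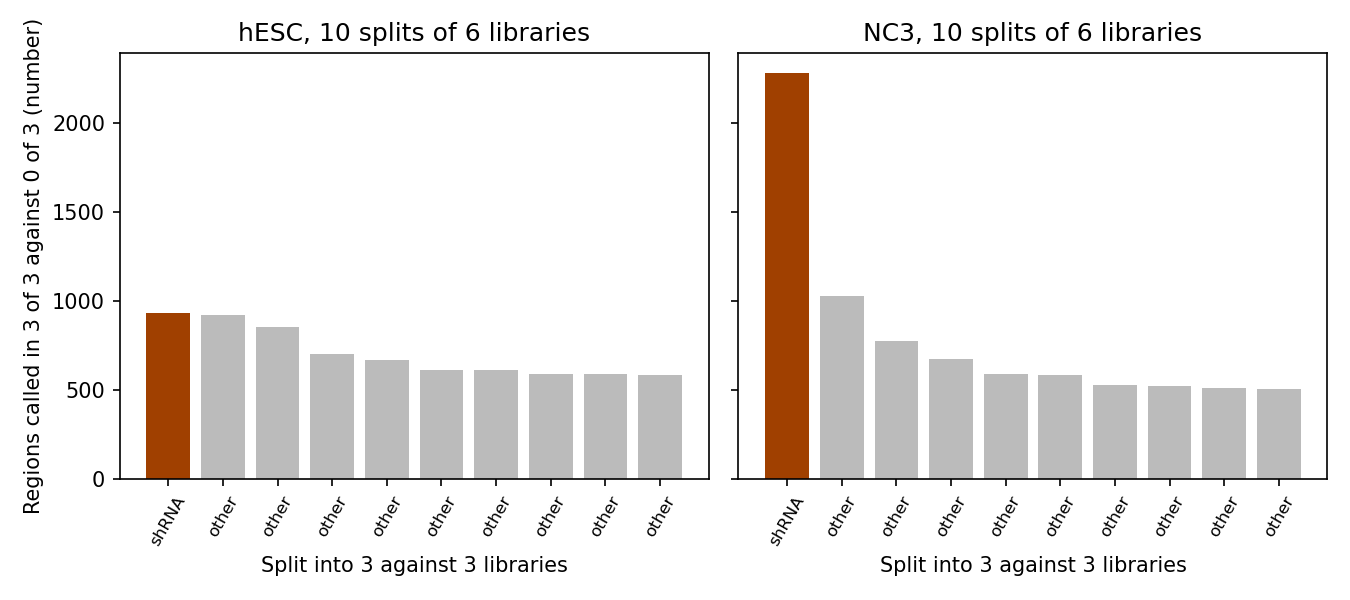
Number of regions called in 3 of 3 libraries on one side and 0 of 3 on the other, for the 10 ways to split the 6 libraries of each stage into 3 and 3, with the split by shRNA in brown and the others in grey. The shRNA split gave 931 in hESC, where the highest other split gave 918, and 2279 at NC3, where the highest other gave 1025.

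In hESC, control-only regions were most numerous at DYNC2H1, a dynein gene of cilia (3), and at KCNAB1, GLRA1, FOXP1, PTPRR, NHSL1, GRIP1, AUTS2, RAB40C and NELL2 (2 each). Regions called only with shOTUD5 were found at HPCAL1, SMARCA2, which encodes a catalytic subunit of SWI/SNF remodellers, GRB14, CCDC85C, PREX1, CDH12, OPCML and TNS3 (2 each) and at WWOX and IFT81 (1 each). FOXP1, a forkhead factor gene, had 13 ± 1.73 called regions in control and 8.33 ± 1.53 in shOTUD5 libraries, and HPCAL1 had 3 ± 1.73 and 7 ± 1.73 (SD, n = 3). Totals were closer at others, such as KCNAB1 (10 ± 1.73 and 9 ± 2.65) and SMARCA2 (10 ± 2 and 11.3 ± 1.53). All these totals include the separated regions by which the genes were picked. The numbers of separated regions were 405 control-only and 526 shOTUD5-only, 931 in all or 13.2% of 7049 regions with calls in 3 of 6 libraries, where chance gives 10%. Another split gave 918, and without control replicate 1 or 2 or shOTUD5 replicate 1 or 3 another split gave more than the shRNAs did (1969 and 2073, 1939 and 2039, 2177 and 2300, 2011 and 2288, shRNA split first). With lists of equal length the shRNA split gave 942 and the highest other 663.

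Over both stages, no gene and no region passed the comparison of the shRNAs. Members of the neural crest list had 18.5 ± 1.08 regions per 10000 in hESC control and 17.5 ± 0.637 in hESC shOTUD5 libraries, and 26.8 ± 0.841 and 24.9 ± 0.108 at NC3 (SD, n = 3). This difference of −1.44 had an exact permutation p of 0.015 and an adjusted p of 0.18, with adjusted p from 0.06 to 1 over the alternatives, so it failed the correction. A list that differs alone cannot go below an adjusted p of 0.06, because the smallest p of this permutation test is 0.005. PAX3 had 10 ± 1.73 and 6.67 ± 1.53 called regions at NC3 (exact permutation p = 0.065 over both stages) and ZEB2, a neural crest and neural factor gene, 9 ± 1.73 and 6 ± 1 (p = 0.045, adjusted p = 0.934). Not every member went this way. Another member of this list had 4 ± 1 regions in hESC control and 6 ± 1 in hESC shOTUD5 libraries, and 5.67 ± 0.577 and 5.67 ± 1.53 at NC3. Its exact permutation p over both stages was 0.04, with an adjusted p of 0.934. Adjusted p for the other 11 lists was 0.98, among them pluripotency with 11.2 ± 0.841 and 11.1 ± 1.48, and neuroectoderm with 28.5 ± 1.31 and 27.1 ± 1.14 at NC3. Of 2736 regions tested, 0 passed the exact stratified permutation test (smallest adjusted p = 0.615), and at an unadjusted p below 0.05 there were 48 called more often and 41 less often with shOTUD5. Of 12478 genes, 0 passed the exact permutation test (smallest adjusted p = 0.79). At an unadjusted p below 0.05 there were 275 higher and 318 lower. How many genes other labellings give at that threshold was not computed, so these counts were not set against chance. The smallest p of this permutation test is 0.005, so no gene can pass the adjustment unless a great many reach it. No shRNA change was simulated for genes, so how many changed genes could be missed is unknown. Simulated data gave no calls with 200 changed regions, so a number of that size could not have been seen.

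On average, libraries with the same shRNA shared more called regions than libraries with different shRNAs. Within NC3, called regions had a mean Jaccard index of 0.66 among control, 0.635 among shOTUD5 and 0.605 between control and shOTUD5 libraries, and within hESC 0.609, 0.619 and 0.604. The within minus between difference over both stages was 0.0263 (exact one-sided permutation p = 0.01, the smallest possible). It was 0.0426 at NC3 and 0.01 in hESC, each with the smallest possible permutation p of 0.1. Single pairs overlapped: between shRNAs the index ranged from 0.578 to 0.645 in hESC, where control replicate 3 with shOTUD5 replicate 2 was above the highest pair within an shRNA (0.624). At NC3 it ranged from 0.566 to 0.636 between shRNAs and from 0.616 to 0.683 within them. Between stages the mean index was from 0.345 to 0.378.

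The share of stage regions called in each library was also compared between the shRNAs. Stage regions were picked on both arms together, and each was called in at least 5 of the 6 libraries of its higher stage, so a region called in fewer than 2 of the 3 shOTUD5 libraries of that stage cannot be among them. These shares therefore do not show whether stage regions were called as completely with shOTUD5. Of the NC3-higher regions, NC3 control libraries had called 96.4% and NC3 shOTUD5 libraries 94.4%, and in hESC 2.33% and 1%. Of the hESC-higher regions, hESC control libraries had called 93.2% and hESC shOTUD5 libraries 95.3%, and at NC3 1.76% and 2.61%. The shRNA difference over both stages was −1.65 percentage points for NC3-higher regions (exact two-sided permutation p = 0.145) and 1.46 for hESC-higher regions (p = 0.225). By the same exact permutations, lists of equal length gave −1.44 (p = 0.005) and 1.51 (p = 0.035), leaving out NC3 shOTUD5 replicate 3 gave −3.09 (p = 0.02) and leaving out hESC control replicate 3 gave 2.68 (p = 0.04). Dividing by the share of other regions turned both signs (0.0529, exact permutation p = 0.59, and −0.012, p = 0.815).

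Separated regions differed in how often they were called at the other stage. Averaged over regions, hESC control-only regions were called in 52.5% of the NC3 libraries and hESC shOTUD5-only regions in 19.6%. The difference was 33 percentage points, where the other splits gave at most 18.5. Of these hESC regions, 135 control-only and 26 shOTUD5-only ones were called in all 6 NC3 libraries. NC3 control-only regions were called on average in 12% of the hESC libraries and shOTUD5-only regions in 29.9%, a difference of 17.9, and another split gave 18. For all regions with calls in 3 of 6 libraries, the averages were 31% for hESC regions and 29.9% for NC3 regions. At NC3 the shOTUD5-only regions thus lay at that average and the control-only regions below it. In hESC the control-only regions lay above it and the shOTUD5-only regions below. Few regions were separated at both stages: 4 control-only and 5 shOTUD5-only regions agreed in direction, where 2.83 and 2.5 arise by chance, and 6 were opposite.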

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

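Of the tests in this part, those of chance for the stage regions and for the shRNA regions over both stages, and that of hESC-state cells at NC3, were set before their results were seen, and the others after.

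The share of a library's called regions that were also called in at least 1 library of the other stage moved with the shRNA in opposite directions at the 2 stages, and the test of that difference is why it stands here. In hESC it was 73.8 ± 1.71% with control and 70.5 ± 1.36% with shOTUD5, and at NC3 62.3 ± 1.12% and 65.4 ± 0.479% (SD, n = 3, exact permutation p = 0.1 at each stage, the smallest possible). The shRNA effect was 6.42 percentage points higher at NC3 than in hESC (exact two-sided permutation p = 0.005, the smallest possible). Adjusted over the 18 interactions tested, the permutation p was 0.09, so it fails the correction. An interaction that differs alone could not have passed, since 0.09 is the lowest adjusted p it can reach. The mean Jaccard index with the other stage gave an interaction of 0.0324 (p = 0.025 by exact permutation), with shRNA differences of −0.0184 in hESC (p = 0.1) and 0.014 at NC3 (p = 0.3), where the libraries of the 2 shRNAs overlapped.

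With lists of equal length the difference was 4.44 (exact permutation p = 0.025), which argues against list length as its whole source. In hESC, the 135 control-only regions called in all 6 NC3 libraries had a median percentile of 77.8 in the NC3 lists, above the highest of 18 sets from other splits, 71.8, so a few cells in the NC3 state among the hESC control cells may account for that part. At NC3, the 108 shOTUD5-only regions called in all 6 hESC libraries had a median of 63.1 in the hESC lists, between the median of 55.6 and the highest of 74.9 of the other sets, which leaves open whether more cells stayed in the hESC state with shOTUD5. A difference in how far the cells had moved from one state to the other, which the shRNA could bring about, was not tested apart from a mixture of cells and stays open, as do handling differences that the labels do not record.

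At NC3 the shRNA split gave 2279 separated regions and the highest of the other 9 splits 1025, and 10 splits are too few for a share below 0.05. With lists of equal length it gave 2135 against at most 583, which argues against list length as the whole source. Without NC3 shOTUD5 replicate 2, the shortest NC3 list, it gave 3716 against at most 2386, which argues against that library alone, though by little, and without NC3 shOTUD5 replicate 3 it gave 4072 against 2884. Of the 89 NC3-separated regions with 3 of 6 calls in hESC, 10.1% were separated the same way there, so a fixed difference in DNA between the control and shOTUD5 cells is unlikely to account for those 89, while the rest were not open to this test. An effect of the shRNA, on OTUD5 or on other transcripts, and a difference in culture or preparation between the arms remain open, since each arm had 1 shRNA and no batch is recorded.

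For the stages, 1 of 100 splits of the 12 libraries, the labelled one, gave 17061 called regions and the highest other gave 0. The same held for the 1082 called genes (1 of 100, highest other 0), which argues against chance for both counts. In simulations 200 changed regions or genes also gave 0 calls, so another split can give 0 without being free of differences. For the shRNA over both stages the labelled split gave 0 regions, a number that 100 of 100 splits reach by construction, so this count says nothing about chance. At an unadjusted p below 0.05 its 89 regions were reached by 6 of 100 splits, the labelled one included, with a highest other of 136. In hESC the shRNA split gave 931 separated regions and the highest other 918 (1 of 10 splits), and with lists of equal length 942 and 663, with too few splits for a share below 0.05.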

How the results depend on the processing

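Of 227 results under settings that kept every library, 195 kept their direction and their side of the threshold, or stayed within the bounds set for counts, and of 408 with a library left out 354 did. The 354 include counts of separated regions with a library of the other stage left out, which could not change. The nearest gene end, the settings for the covered length and those for the share also called at the other stage were added after the data had been seen. For the results below the cause was not tested unless given. Plain numbers of regions gave 5 stage-dependent lists in place of 8. Adjusting over all regions gave 10060 stage regions (6840 and 3220), because then none but regions called 6 to 0 can pass. Equal-length lists gave a gene-end difference between stages of −0.4534, and shRNA differences in the share of stage regions called, a share limited by how these regions were picked, of −1.438 and 1.508, while dividing by the share of other regions gave 0.05285 and −0.01205. Surface ectoderm turned from −0.0773 to 1.451 (regions within 50 kb, adjusted p = 0.0462 by exact permutation), 4 (plain numbers) and 0.2872 (nearest gene end), and stromal genes to 4.333 (plain numbers). The YAP, TEAD and AP-1 targets turned to −0.3444 (equal-length lists), −0.0009505 (fixed windows), −0.1312 (regions in at least 2 libraries), −1.527 (genes within 20 kb, adjusted p = 0.0195 by exact permutation), −0.594 (within 50 kb) and −0.04842 (nearest gene end). Neuronal differentiation passed with 50% of a region covered (2.384), fixed windows (1.704) and regions in at least 2 libraries (1.767). It passed under no other setting that kept every library, with 1.38 for equal-length lists, 0.2982 for genes within 20 kb and 0.8629 for the nearest gene end (exact permutation adjusted p = 0.124, 0.659 and 0.133). HOX missed the threshold with genes within 20 kb (−0.5905). The motif settings were not run. Depth is unknown, so which absent calls reflect low depth could not be judged.

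Leaving out 1 library at a time gave stage differences in peaks from 3562 to 6312 and shRNA differences from −2060 to 681. Separated regions ranged from 931 to 2313 in hESC (405 to 1089 control-only and 526 to 1534 shOTUD5-only) and from 2279 to 4138 at NC3 (1531 to 3140 and 748 to 1777), since 3 against 2 libraries separate more easily. The share of NC3-higher regions ranged from −3.089 to −0.8223 and of hESC-higher regions from 0.8283 to 2.675, and the gene-end difference between shRNAs from −0.2856 to 0.04516. List differences between stages ranged from −0.3189 to 0.1591 for surface ectoderm, −0.2854 to 0.4183 for YAP, TEAD and AP-1 targets and −0.5469 to 0.1662 for stromal genes.

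The groups share replicate numbers, which pair nothing by the labels. Deviations of same-numbered libraries correlated from −0.016 to 0.036 over regions, and in 7 of 24 comparisons a library correlated best with its own number. With the replicate number as a block, 10060 stage regions were called (6840 and 3220). These are the regions called 6 to 0, since the block lets no other region pass, so this count says nothing about pairing. Under the block the covered length differed by 4.39 Mb (exact p = 0.0625), similarity by 0.0263 (p = 0.0625, the smallest the block allows for it, so it could not pass) and the share of NC3-higher regions by −1.655 (p = 0.0312). Among the other values per library, the gene lists and the shRNA regions over both stages, the block changed no call. The test per gene and the counts of separated regions were not run with it.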

Other observations

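The regions that separated the shRNAs were also counted by gene list, a measure chosen after the data had been explored. At NC3, 6 control-only regions lay at targets of YAP, TEAD and AP-1, where 2.49 arise by chance (Fisher's exact test, two-sided, p = 0.0247, adjusted p = 0.296 over 12 lists), 3 shOTUD5-only regions did where 1.22 arise by chance (exact p = 0.115), and no list passed at either stage or in either direction. In hESC, 4 shOTUD5-only regions lay at neuroectoderm genes, where 1.49 arise by chance (exact p = 0.0571, adjusted p = 0.685). At NC3, ATF3 had 7.67 ± 0.577 called regions with control and 5.33 ± 0.577 with shOTUD5, TEAD1 13.7 ± 1.53 and 11 ± 1, FOSL2 3 and 4.33 ± 0.577, and SALL4, a pluripotency factor gene, 3.33 ± 0.577 and 1 (SD, n = 3). Over both stages these had exact permutation p of 0.04, 0.035, 0.01 and 0.025, and adjusted p of 0.934, 0.919, 0.852 and 0.852, so none passed.

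Other members with values apart at NC3 were VTCN1, with 2 ± 1 called regions in control and 5 in each shOTUD5 library, TNFRSF19, with 7.33 ± 0.577 and 5.33 ± 0.577, and BAMBI, a BMP and activin pseudoreceptor gene, with 2 ± 1 and 0.333 ± 0.577 (SD, n = 3, exact permutation p = 0.025 over both stages and adjusted p = 0.852 for each). No chromosome's share of called regions passed between the shRNAs, with a smallest exact permutation p of 0.04 for chromosome 12 (5.03% and 4.94%) and an adjusted p of 0.6. Stage regions ranked in the middle of their lists, with a median percentile of 54 for NC3-higher and 50 for hESC-higher regions.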
